A study of Mus musculus with 7 samples.

How the data were processed

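RNA sequencing was analysed from 7 libraries of primary mouse ovarian granulosa cells. Per the labels' protocols, 3-week-old female mice received 5 IU of pregnant mare serum gonadotropin (PMSG), which drives follicle growth, and 48 h later 5 IU of human chorionic gonadotropin (hCG), which triggers ovulation. Per the labels' protocols, poly(A) RNA was selected, broken to fragments of about 200 bp, made into libraries with a NEBNext Ultra kit and read as pairs of 150 bp. Per the series' design text, 2.5 µg of RNA from each genotype was used. The labels do not give the time from hCG to collection, and they do not say whether each library came from a separate animal. The p-values therefore measure only the spread between these samples.

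The 4 WT libraries carried the genotype Ezh2flox/+; Cyp19-Cre and the 3 KO libraries the genotype Ezh2flox/flox; Cyp19-Cre, per the labels. Cyp19-Cre expresses the Cre recombinase from the promoter of aromatase, so both groups carried Cre and the WT group 1 floxed allele. The treatment label of WT4 was that of the KO group, while its title and genotype were those of WT. It was kept in WT and left out in an alternative.

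The table deposited by the authors held FPKM, fragment numbers scaled to transcript length and library depth, for 50095 genes. No label or header named the unit, and it was inferred from the values, which were not whole and whose sums differed between libraries and lay far below those of CPM or TPM. Per the submitters' processing notes, FastQC, Trimmomatic, HISAT2, HTSeq 0.12.4, DESeq2, edgeR and the build mm10 were used, with no role or order given. Which of these made the FPKM values is not stated. The table held 43339 genes with an Ensembl identifier, of which 42456 were in the GENCODE vM21 annotation of GRCm38 (mm10), and 6756 gene models without one. Coordinates and transcript lengths came from that annotation, and symbols from the deposited table. The length of a gene was that of its longest transcript.

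The design fixed in advance assumed counts. The table held none, so its stated substitute was used, limma-trend on log2(FPKM + 1), and no count test was run. The rule for named genes had asked for a mean count of at least 20 and for separation in CPM, and a mean of at least 1 FPKM and separation in FPKM took their place. A fold change on this scale understates the change of genes near or below 1 FPKM. Depth was estimated from the size of 1 fragment in rarely seen genes with a single transcript longer than 600 bp. These estimates lay between 34.2 and 42.0 M (mega) fragments per library and are approximate. Only 7.30% to 11.1% of those low values lay within 2% of a whole multiple, so counts were not recovered and no counting intervals are given.

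Genes with a mean of at least 1 FPKM over the 7 libraries were tested, 13850 in all, of which 566 were gene models without an Ensembl identifier. This mean covers both groups, so a gene of low level could pass through the values of 1 group alone. Of all genes, 32922 had a value above 0 in some library. KO-labelled minus WT libraries was fitted with limma 3.58.1 in R 4.3.3 with a mean-variance trend. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene is from limma, and every interval is a 95% interval from the same fit. Differences of single values per library were tested with a two-sided exact permutation test over the 35 ways to split 7 libraries into 4 and 3, whose smallest possible p is 0.0286.

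The gene lists, 30 in all, were tested with limma's camera, which compares a list with the other genes. A preset correlation of 0.01 between genes was used, with adjustment over the 28 lists that had at least 5 tested genes. Camera with a correlation estimated per list and limma's fry, which asks whether the genes of a list move one way on balance without comparing them with other genes, were alternatives. An exact permutation of each list's median over the 35 splits was added after the data were seen. Counts of changed members are given over all genes tested and adjusted over the list alone.

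The groups, the substitute test, the threshold, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Ezh2 and Il1r2, the 12 largest rises and the 12 largest falls among called genes with a symbol and with every KO-labelled library beyond every WT library, the 6 smallest p-values in each direction, and up to 4 called members of each list, or for a list with none the 2 of highest mean. Predicted gene models and pseudogenes were left out of the largest changes. Genes named outside the rule are said to have been chosen after their values were seen.

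The alternatives tried were a pseudocount of 0.1, no filter, median-of-ratios and upper-quartile scaling, the fit without the 20 genes of highest mean, the replicate number as a block, and each library left out in turn. The fit without the 20 genes of highest mean also scaled each library to an equal sum of the remaining FPKM. Added after the data were seen were a minimum mean of 5 FPKM, scaling to an equal sum of FPKM, quantile normalization, robust empirical Bayes, the fit without genes under 200 bp and unannotated gene models, and a correction of each library for a smooth trend with transcript length (loess, span 0.3). The planned count tests were not run. The fit was tested on simulated data made from 13850 genes. It recovered 12 of 67 genes changed 1.5-fold, 41 of 67 changed 2-fold and 57 of 66 changed 3-fold, with 6 false calls among 13650 unchanged genes. In the simulated list test the shifted list was called and 0 of the other lists were. The simulated noise was independent between genes, with no trend with transcript length. In the real data the estimated correlation within a list reached 0.85, for the oocyte markers. The simulation therefore does not show how often lists are called falsely here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.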

Results

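Gene expression was measured in granulosa cells, the somatic cells that surround and support the oocyte, from ovaries of mice primed with PMSG and then hCG. The series asks what changes in these cells when Ezh2, which encodes the histone methyltransferase of Polycomb repressive complex 2 (PRC2), is deleted by Cyp19-Cre, and its title also names the decoy interleukin-1 receptor Il1r2. It compares 4 libraries labelled WT (Ezh2flox/+; Cyp19-Cre) with 3 labelled KO (Ezh2flox/flox; Cyp19-Cre). Levels are given as mean ± SD in FPKM, over n = 4 WT and n = 3 KO-labelled libraries. Estimated depth was 35.7 ± 0.768 M (mega) fragments in WT and 37.6 ± 3.95 M fragments in KO-labelled libraries (two-sided exact permutation p = 0.429). These estimates are approximate. The size of 1 fragment was searched only within a set range, and few low values lay near its whole multiples. They therefore do not show that depth was equal. The sum of FPKM over all genes was 379279 ± 8076 in WT and 421616 ± 25603 in KO-labelled libraries (exact permutation p = 0.0286, the smallest possible with 35 splits). Spearman correlations across genes were 0.965 to 0.981 among WT libraries, 0.961 to 0.976 among KO-labelled libraries and 0.903 to 0.957 between the groups. The first principal component held 56.5% of the variance and placed the WT libraries between -31.4 and -14.4 and the KO-labelled libraries between 19.1 and 43.2.

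The targeted gene was measured first in every library. Ezh2 (ENSMUSG00000029687, GRCm38 chromosome 6, 47530139 to 47595341, minus strand) stood at 20.5, 23.4, 25.2 and 25.3 FPKM in WT1 to WT4 and at 20.03, 17.8 and 26.15 FPKM in the libraries labelled KO1 to KO3, so the library labelled KO3 held the highest value of all 7. The group levels of 23.6 ± 2.27 and 21.3 ± 4.32 FPKM differed by less than the spread between libraries (log2 difference -0.15, SE 0.14, 95% interval -0.46 to 0.16, limma adjusted p = 0.432). Ezh2 therefore did not set the KO-labelled libraries apart, and every direction given here follows the labels. A whole-gene FPKM also takes fragments from exons outside the deleted part, and no values per exon were in the table. Il1r2 (ENSMUSG00000026073, chromosome 1, 40074079 to 40125231, plus strand), a receptor that binds interleukin-1 without signalling, was near the floor of the test at 1.86 ± 0.652 FPKM in WT and 2.01 ± 0.452 in KO-labelled libraries. Its log2 difference of 0.09 (SE 0.19, 95% interval -0.34 to 0.51, limma adjusted p = 0.752) turned to -0.011 with an equal sum of FPKM and to -0.032 without KO1.

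**Figure D1:**
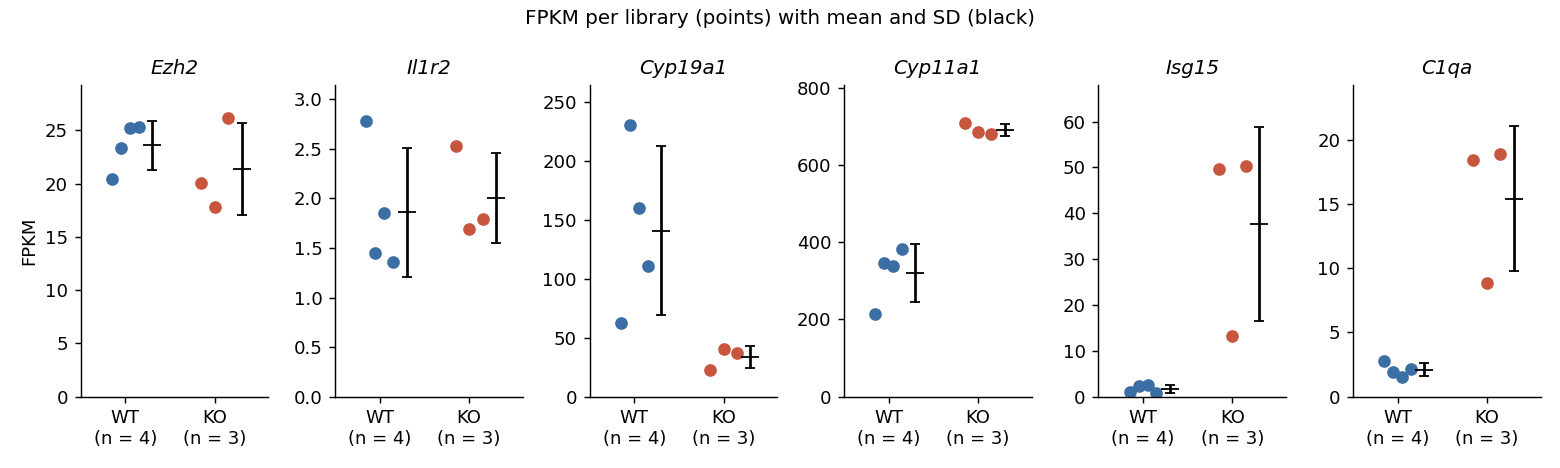
FPKM (y axis, linear, from 0) of Ezh2, Il1r2, Cyp19a1, Cyp11a1, Isg15 and C1qa in each library (points) with the group mean and SD (black), for 4 WT and 3 KO-labelled libraries. Ezh2 and Il1r2 overlapped between the groups, Cyp19a1 was 141 FPKM in WT and 33.4 in KO-labelled libraries, and Cyp11a1, Isg15 and C1qa were higher in every KO-labelled library than in every WT library.

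Across the transcriptome, most changes of at least 2-fold were rises. Isg15, an interferon-induced ubiquitin-like protein, rose from 1.64 ± 0.900 to 37.7 ± 21.2 FPKM (log2 3.72), and Cyp19a1, the aromatase that makes estrogens, fell from 141 ± 71.6 to 33.4 ± 9.46 FPKM (log2 -1.93). Of 13850 genes tested, 3410 (24.6%) were called by limma, 1095 higher and 2315 lower, and 469 of these changed at least 2-fold, 380 higher and 89 lower. At an unadjusted p under 0.05 there were 5542 genes. Every KO-labelled library lay beyond every WT library for 36.3% of the genes tested, against 5.71% by chance, and for 3301 of the called genes. The call count was 2022 without WT2, 1552 without WT3, 1293 without KO1 and 1865 with no filter on low values, and the 2-fold count was 307 without KO1, 780 with a pseudocount of 0.1 and 243 with a minimum mean of 5 FPKM. The split of the calls depended on scaling. Higher genes were 32.1% of the calls, 51.9% with median-of-ratios scaling (1593 higher, 1477 lower), 44.2% with upper-quartile scaling (1422 higher, 1792 lower), 17.9% with an equal sum of FPKM (858 higher, 3938 lower) and 54.1% after the length correction (1602 higher, 1357 lower). Among 2-fold calls 81.0% were higher, against 65.8% with a pseudocount of 0.1 and 61.2% with an equal sum of FPKM. The median log2 difference of all genes was -0.08, and -0.21 with an equal sum of FPKM.

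The change also followed transcript length. In the shortest of 5 equal bins of genes, with transcripts up to 1569 bp, 309 were higher and 169 lower, and in the longest bin, from 5055 bp, 75 were higher and 745 lower. Across 13212 genes with an annotated length, which are not independent replicates, the Spearman correlation of log2 difference and length was -0.279.

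**Figure D2:**
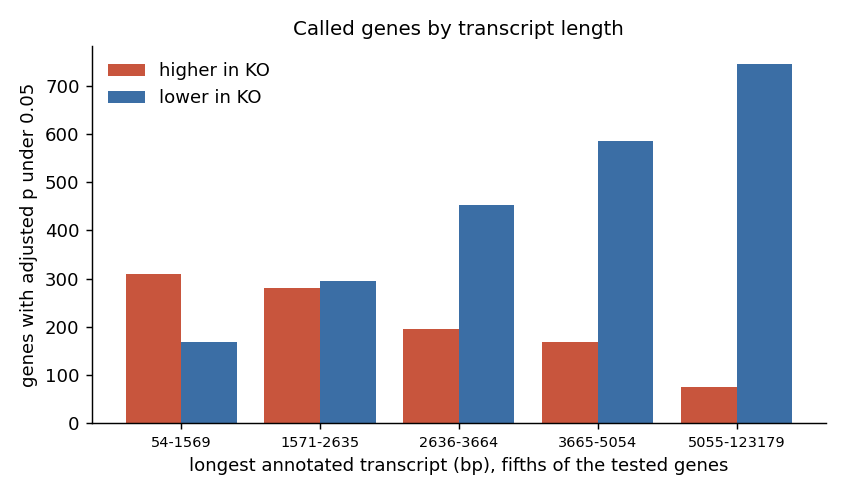
Genes called higher and lower in KO-labelled libraries (y axis, number of genes) in 5 bins of transcript length (x axis, equal shares of 13212 genes from the shortest to the longest). Lower calls went from 169 in the shortest bin to 745 in the longest, and higher calls from 309 to 75.

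Of the 28 lists tested, camera called 18, of which 16 were higher and 2 lower in KO-labelled libraries. With an estimated correlation it called 0 (smallest adjusted p = 0.283, 2 lists at an unadjusted p under 0.05), while fry called 13. The exact permutation of list medians called 0 after adjustment (smallest adjusted p = 0.0714), although 12 of all 30 lists had their largest median difference in the real split alone, at an unadjusted p of 0.0286. Some lists called by camera were not among these. The unadjusted permutation p was 0.0571 for the granulosa and antioxidant lists, 0.0857 for the LH-induced list and 0.114 for the inflammatory and steroidogenesis lists, and others are given below.

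**Figure D3:**
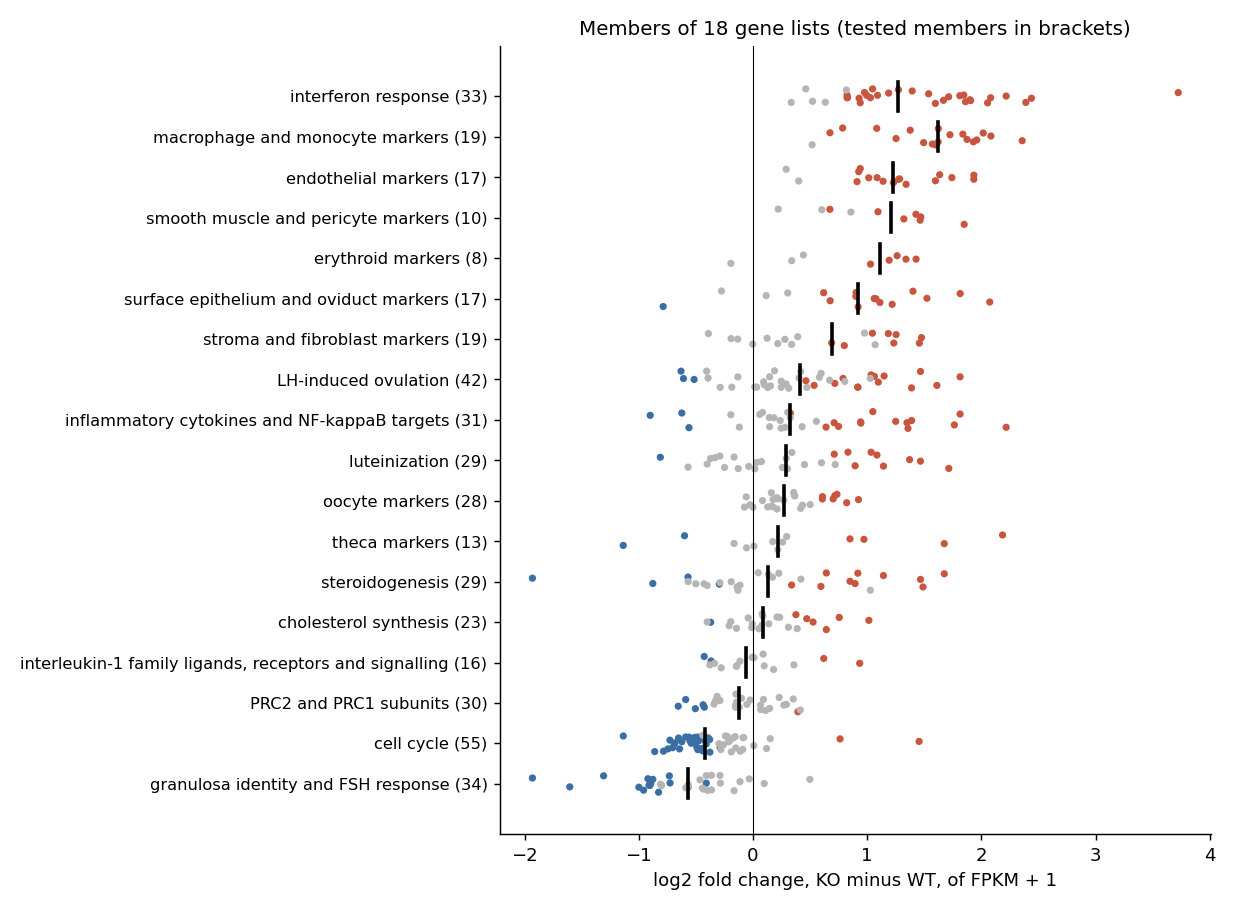
Log2 difference of KO-labelled minus WT libraries (x axis) on the log2(FPKM + 1) scale for the tested members of 18 of the 30 gene lists (y axis, called by camera or not), with red points for genes called higher, blue for lower, grey for those not called and a black bar at the list median. Macrophage, interferon, endothelial and smooth muscle lists had medians from 1.21 to 1.62, and the granulosa and cell cycle lists -0.57 and -0.42.

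Interferon-response genes were higher in KO-labelled libraries as a group. Of 33 tested members 28 rose and 0 fell (31 and 0 adjusted over the list alone), with a median log2 difference of 1.27. Isg15 rose as given above (limma adjusted p = 0.00330), the chemokine Cxcl10 rose from 1.02 ± 0.464 to 8.91 ± 4.61 FPKM, and the class I antigen presentation genes B2m and H2-K1 rose from 159 ± 10.9 to 366 ± 57.4 and from 85.7 ± 5.73 to 153 ± 12.2 FPKM. Camera gave an adjusted p of 1.4e-20 for the list, and adjusted p = 0.283 with an estimated correlation. In the same libraries the macrophage markers described next rose by a median of 1.62, and 9 of the interferon genes stood at 5 FPKM or more in WT. With a minimum mean of 5 FPKM over both groups 15 members were tested, some only through their KO-labelled values, and 13 rose.

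Markers of several other ovarian and blood cell types rose. Macrophage and monocyte markers rose in 18 of 19 tested members and fell in 0 (19 and 0 adjusted over the list alone, median 1.62), among them the complement gene C1qa, from 2.09 ± 0.516 to 15.4 ± 5.68 FPKM, and the lysosomal protease Ctss, from 2.04 ± 0.502 to 11.8 ± 4.37 FPKM. Endothelial markers rose in 15 of 17 and fell in 0 (16 and 0 adjusted over the list alone, median 1.23), with the adhesion molecule Pecam1 at 2.30 ± 0.299 and 6.75 ± 0.811 FPKM and the co-receptor Eng at 2.00 ± 0.988 and 10.2 ± 2.03 FPKM. Smooth muscle and pericyte markers rose in 7 of 10 and fell in 0 (9 and 0 adjusted over the list alone, median 1.21), led by the actin-binding Tagln at 24.2 ± 5.67 and 98.1 ± 55.2 FPKM. Surface epithelium and oviduct markers rose in 13 of 17 and fell in 1 (13 and 1 adjusted over the list alone, median 0.92), with the keratin Krt18 at 5.67 ± 0.588 and 23.8 ± 9.61 FPKM. The fall was Ovgp1, an oviduct glycoprotein, named after its value was seen, and not called without WT3, WT4, KO1 or KO3, with no filter or after the length correction. Camera's adjusted p was 1.1e-16, 1.8e-14, 1.6e-06 and 9.0e-08 for these 4 lists, and for each adjusted p = 0.283 with an estimated correlation. In WT libraries 2 macrophage, 2 endothelial, 2 smooth muscle and 5 epithelial markers stood at 5 FPKM or more. With a minimum mean of 5 FPKM over both groups, 8, 5, 4 and 8 members of the macrophage, endothelial, smooth muscle and epithelial lists were tested. Of these 7, 4, 4 and 7 were higher. Some members passed that minimum only through their KO-labelled values, so these counts do not show that the rises hold among well expressed genes. Smooth muscle rises numbered 4 with no filter on low values, where the median was 0.60.

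Some stromal, erythroid and oocyte markers rose as well. Stroma and fibroblast markers rose in 8 of 19 and fell in 0 (9 and 1 adjusted over the list alone, median 0.69), with the actin-severing Gsn at 6.90 ± 2.03 and 21.1 ± 6.79 FPKM, and 12 of the 19 were also in another list. Erythroid markers rose in 5 of 8 and fell in 0 (6 and 0 adjusted over the list alone, median 1.11). The globin Hbb-bs went from 373 ± 153 to 969.5 ± 230.4 FPKM, uncertain where reads were shared with its near-identical copies, and the erythroid haem synthesis enzyme Alas2 from 6.01 ± 1.31 to 13.2 ± 1.59 FPKM. Oocyte markers rose in 7 of 28 and fell in 0 (7 and 0 adjusted over the list alone, median 0.27), with Rfpl4 at 21.5 ± 3.73 and 41.9 ± 9.14 FPKM, and 27 of the 28 stood at 5 FPKM or more in WT. Camera's adjusted p was 6.5e-05, 0.000212 and 3.0e-06 in that order, and adjusted p = 0.317, 0.283 and 0.417 with an estimated correlation. Stromal rises numbered 5 without WT3, 3 without KO1 and 5 without KO3, erythroid rises 3 without each of WT3, KO1 and KO3, and oocyte rises 4, 3 and 2 without WT3, KO1 and KO3. With no filter on low values the 3 lists had 3, 2 and 2 rises, and the stromal and erythroid medians were 0.36 and 0.74. With a minimum mean of 5 FPKM 5 stromal markers rose and their median was 0.39. The oocyte median was 0.17 without WT2 and 0.13 with an equal sum of FPKM. Taken per library against the WT mean, the oocyte median was 0.31 in WT1, above KO1 (0.22) and KO2 (0.21) but below KO3 (0.43). The stromal median was 0.58 in WT2, above KO2 (0.28) but below KO3 (0.59) and KO1 (0.76). The exact permutation of list medians gave an unadjusted p of 0.200 for the oocyte list. It gave 0.0571 for the stromal and for the erythroid list.

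Theca markers were mixed, with 4 higher and 2 lower of 13 (4 and 2 adjusted over the list alone, median 0.22). The theca hormone Insl3 rose from 1.002 ± 0.469 to 8.75 ± 5.25 FPKM and the hedgehog receptor Ptch1 fell from 11.7 ± 1.75 to 4.75 ± 0.729 FPKM. Camera did not call the list (adjusted p = 0.0641), but did so without WT2 (0.0165) or KO3 (0.0393), without the 20 genes of highest mean (0.0370) and with an equal sum of FPKM (0.0194). The median was 0.12 without WT4, 0.12 without KO1, 0.39 without KO2 and 0.092 with an equal sum of FPKM, and 2 were higher with no filter. Of neutrophil and of lymphocyte markers only 4 each were expressed enough to be tested, too few for camera. In each of these lists 2 were higher and 0 lower (2 and 0 adjusted over the list alone), with the histidine decarboxylase Hdc at 3.39 ± 0.540 and 8.82 ± 2.23 FPKM. The neutrophil rises numbered 1 without each of WT2, WT3 and KO1, and the lymphocyte rises 1 without WT2, 1 without WT3 and 0 without KO1 or KO3.

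Granulosa identity and FSH-response genes fell. None of the 34 tested members rose and 15 fell (1 and 22 adjusted over the list alone, median -0.57). Besides Cyp19a1 (chromosome 9, limma adjusted p = 0.0113, and 0.0524 with no filter), the estrogen receptor Esr2 fell from 56.9 ± 4.38 to 30.2 ± 4.07 FPKM (log2 -0.90, adjusted p = 0.00367), Kctd14 from 47.1 ± 3.45 to 18.9 ± 5.47 FPKM (log2 -1.31, adjusted p = 0.00402), and the growth factor Igf1 from 19.6 ± 1.80 to 11.4 ± 1.22 FPKM (log2 -0.73). Other granulosa genes were not called. Inha, an inhibin subunit, was at 3222 ± 389 and 2389 ± 315 FPKM (adjusted p = 0.0799), and the granulosa fate factor Foxl2 at 17.3 ± 3.03 and 13.2 ± 2.60 FPKM (adjusted p = 0.138), both looked up after the results were seen. Camera gave the list an adjusted p of 7.6e-06, and adjusted p = 0.283 with an estimated correlation. The number of members that fell was 9 without WT3, 6 with no filter and 23 with an equal sum of FPKM. In the same libraries macrophage and endothelial markers rose by medians of 1.62 and 1.23.

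Cell cycle genes also fell, in 33 of 55 tested members, while 2 rose (36 falls and 2 rises adjusted over the list alone, median -0.42). The proliferation antigen Mki67 fell from 26.8 ± 5.44 to 11.6 ± 1.87 FPKM, the topoisomerase Top2a from 57.4 ± 5.99 to 31.4 ± 5.25 and the ribonucleotide reductase subunit Rrm1 from 26.5 ± 1.33 to 16.2 ± 2.19. The rises were the G1 cyclin Ccnd1, from 1.15 ± 0.260 to 4.94 ± 1.14 FPKM, and Ccnd3, named after its value was seen. Camera gave an adjusted p of 1.3e-07, and adjusted p = 0.306 with an estimated correlation. The falls numbered 18 without KO1, 19 without WT3 and 20 with no filter. Endothelial markers rose by a median of 1.23 in the same libraries.

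Genes of the ovulatory and luteal programmes rose in part. Of 42 LH-induced genes 14 rose and 3 fell (14 and 4 adjusted over the list alone, median 0.41), with the morphogen Bmp2 at 11.7 ± 1.33 and 25.5 ± 1.58 FPKM, the protease inhibitor Timp1 at 28.6 ± 3.82 and 64.3 ± 4.64 and the nuclear receptor Nr4a3 at 3.94 ± 1.02 and 13.9 ± 1.75. Other ovulatory genes, looked up after the results were seen, were not called, including Ptgs2 at 133 ± 65.9 and 158 ± 97.54 FPKM (limma adjusted p = 0.746) and Areg at 276 ± 45.9 and 332 ± 89.9 (adjusted p = 0.349). Of 29 luteinization genes 9 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.29). Cyp11a1, which cleaves the cholesterol side chain in the opening step of steroid synthesis, rose from 320.1 ± 73.9 to 691 ± 15.4 FPKM (log2 1.14, adjusted p = 0.00679), and the lipoprotein receptor Scarb1 from 339 ± 31.9 to 636 ± 124 FPKM. Camera's adjusted p was 4.2e-06 for LH-induced and 0.000603 for luteinization genes, and for each adjusted p = 0.283 with an estimated correlation. The LH-induced rises numbered 9 without KO1, the falls 1 without each of WT2, WT3, KO1 and KO3, 6 with an equal sum of FPKM and 1 with no filter, median-of-ratios or upper-quartile scaling or the length correction, the luteinization falls 0 without KO1 or KO3 and 2 without WT2 or KO2, and the luteinization call was lost without KO2 (adjusted p = 0.0512). The LH-induced median was 0.14 without WT2, 0.14 without KO2 and 0.26 with an equal sum of FPKM, and the luteinization median 0.16 with an equal sum of FPKM, 0.13 with no filter and 0.074 with a minimum mean of 5 FPKM. Taken per library against the WT mean, the median of the LH-induced genes was 0.67 in KO2 and 0.24 in KO3, but 0.16 in KO1, below the 0.18 of WT4. In the same libraries macrophage markers rose by a median of 1.62.

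Steroidogenesis genes moved both ways. Of 29 tested members 10 rose and 4 fell (11 and 6 adjusted over the list alone, median 0.13). Besides Cyp11a1 and Scarb1, the cholesterol carrier Npc2 rose from 32.6 ± 2.04 to 49.7 ± 1.85 FPKM, and Star, which moves cholesterol into mitochondria and was looked up after the results were seen, from 363 ± 145 to 943 ± 56.7 FPKM (limma adjusted p = 0.00990). Cyp19a1 was among the falls. Camera gave an adjusted p of 0.0224, and adjusted p = 0.290 with an estimated correlation. The call was lost without WT1 (0.0855), without KO2 (0.0639), with the length correction (0.0503) and with quantile normalization (0.121), and the rises numbered 6 without KO3 and with no filter. The median was 0.057 without KO3, 0.024 with an equal sum of FPKM, 0.21 with median-of-ratios scaling, 0.26 after the length correction, 0.077 without the 20 genes of highest mean and 0.046 with no filter. The falls numbered 1 without WT3, 1 without KO1, 2 without KO3, 0 with no filter, 2 with median-of-ratios or upper-quartile scaling and 8 with an equal sum of FPKM. Cholesterol synthesis genes rose in 6 of 23 and fell in 1 (7 and 1 adjusted over the list alone, median 0.09, but -0.06 with an equal sum of FPKM), with Hmgcs1 at 45.5 ± 5.07 and 77.0 ± 2.85 FPKM and Idi1 at 18.5 ± 3.30 and 38.2 ± 5.30. Camera gave that list an adjusted p of 0.00438, and adjusted p = 0.458 with an estimated correlation. Taken per library against the WT mean, its median was 0.20 in WT2, above the 0.040, 0.16 and 0.17 of KO1 to KO3. The exact permutation of list medians gave it an unadjusted p of 0.457. The median was 0.045, 0.21, 0.17, 0.051 and 0.048 without WT1, WT2, KO1, KO2 and KO3, and 0.19 with median-of-ratios scaling, 0.15 with upper-quartile scaling, 0.14 with quantile normalization, 0.25 after the length correction and 0.0081 without the 20 genes of highest mean. The call was lost without KO2 (0.0590), and the rises numbered 3 without WT3, 3 without KO3 and 2 with an equal sum of FPKM or without the 20 genes of highest mean, and the falls 0 with any library but WT1 left out. Theca markers, which share genes with this pathway, were higher in 4 of 13 tested members, and macrophage markers rose by a median of 1.62.

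Inflammatory cytokines and NF-kappaB targets rose in 14 of 31 and fell in 3 (15 and 3 adjusted over the list alone, median 0.33). The monocyte chemokine Ccl2 rose from 0.684 ± 0.447 to 4.79 ± 2.03 FPKM and the stromal chemokine Cxcl12 from 2.05 ± 0.688 to 6.20 ± 1.30. Ccl2 passed the filter only through its KO-labelled values. Camera gave an adjusted p of 9.1e-07, and adjusted p = 0.283 with an estimated correlation. The rises numbered 9 without WT3, 7 without KO1, 8 with no filter and 2 with a minimum mean of 5 FPKM, where the list was not called (0.179), and the falls 1 without KO1. The median was 0.50 without WT1, 0.53 after the length correction, 0.19 with an equal sum of FPKM and 0.15 with a minimum mean of 5 FPKM. Interleukin-1 family genes, the group of Il1r2, moved both ways. Of 16 tested members the cytokine Il18 and the inflammasome adaptor Pycard rose and the kinases Map3k7 and Irak1 fell (2 and 2 adjusted over the list alone). Camera did not call the list (adjusted p = 0.813), whose median was -0.06 and whose mean was 0.0057 (the test's direction was up), and the median was 0.02 with median-of-ratios scaling and 0.06 after the length correction, and -0.00811 without KO1 and -0.17 without KO2. Under the other settings it ran from -0.21 with a minimum mean of 5 FPKM to 0.088 with no filter. Pycard was not called by limma without any of WT1, WT2, WT3, WT4, KO1 and KO3 (adjusted p from 0.0575 to 0.160), Map3k7 and Irak1 not without WT2, WT3 or KO1 (0.0507 to 0.0770 and 0.0501 to 0.0695), and Il18 not without KO1 (0.0683). With no filter Pycard and Il18 were not called, nor was Map3k7 after the length correction, and 4 members were lower with an equal sum of FPKM. In the same libraries macrophage markers rose by a median of 1.62.

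Of 30 tested PRC2 and PRC1 subunits 1 rose and 5 fell (0 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.803). The balance of these counts depended on scaling, with 3 higher and 4 lower under median-of-ratios scaling, 0 and 8 with an equal sum of FPKM, and 5 and 3 after the length correction. The median was -0.12, and under other settings it ran from -0.26 with an equal sum of FPKM to 0.07 after the length correction. The PRC2 accessory protein Mtf2 fell from 20.3 ± 2.19 to 12.6 ± 1.86 FPKM (limma adjusted p = 0.00932), and Ezh1, the paralogue of Ezh2, from 8.82 ± 1.20 to 6.23 ± 0.468 FPKM (adjusted p = 0.0287). The call of Ezh1 was lost without each of WT2, WT3, KO1 and KO2 (0.0647 to 0.0868), with no filter (0.0684) and after the length correction (0.0598). The falls numbered 3 without WT2, 2 without WT3 and 1 without KO1, and the rises 3 without KO2. Of 93 developmental regulators known elsewhere as PRC2 targets only 18 were expressed enough to be tested, and of these 7 rose and 1 fell (7 and 2 adjusted over the list alone, median 0.46). Twist1, a mesenchymal transcription factor, stood at 1.13 ± 0.519 and 9.59 ± 7.07 FPKM, the homeobox gene Hoxd9 at 0.835 ± 0.251 and 4.58 ± 2.29, and Tbx3 at 0.449 ± 0.155 and 2.41 ± 0.984. Hoxd9 and Tbx3 passed the filter, a mean over all libraries, only through their KO-labelled values. The same held for Hoxd8, Hoxd10, Hoxd11, Hoxa7 and Irx5, looked up after the results were seen, whose WT means lay below 1 FPKM. A rise could thus itself bring a member into the test. With no filter 7 of 76 rose and 0 fell. Camera gave an adjusted p of 0.000537, and adjusted p = 0.283 with an estimated correlation. The rises numbered 3 without KO1, 4 without KO3 and 1 with a minimum mean of 5 FPKM, the falls 0 without each of WT2, WT3, KO1 and KO3, and the median was 0.26 without KO3, 0.75 with a pseudocount of 0.1, 0.079 with no filter and 0.078 with a minimum mean of 5 FPKM. Stromal and smooth muscle markers rose in the same libraries by medians of 0.69 and 1.21.

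Among single genes, the largest rise on the log2(FPKM + 1) scale was that of Ifi27l2a, an interferon-induced gene, from 2.80 ± 1.06 to 58.3 ± 41.5 FPKM (log2 3.73, limma adjusted p = 0.00357). Next to Isg15 and Cfd, the adipocyte serine protease adipsin, at 0.111 ± 0.143 and 12.7 ± 12.8 FPKM, stood AU021092 at 2.06 ± 0.527 and 25.2 ± 6.68 FPKM, the metal-binding Mt2 at 37.5 ± 7.16 and 280.2 ± 144, the transcription factor Cebpd at 5.49 ± 0.782 and 45.1 ± 29.2 and the interferon-induced membrane protein Ifitm3 at 17.4 ± 5.98 and 116 ± 53.2. Ly6a, Ly6c1, Ctla2a and Iigp1 completed the largest rises together with Ccl21a, which has near-identical copies and is uncertain. An unannotated gene model rose from 16.7 ± 2.16 to 172 ± 61.3 FPKM with the smallest adjusted p among the rises (0.000960, shared with AU021092). The largest falls held, besides Cyp19a1 and Kctd14, the ferritin receptor Scara5, from 21.5 ± 4.53 to 5.88 ± 2.29 FPKM (log2 -1.74), Ankle1, from 6.72 ± 1.23 to 2.01 ± 0.0303, Foxl2os, the antisense neighbour of Foxl2, from 34.5 ± 11.1 to 12.8 ± 1.55, Sytl3, from 4.18 ± 1.76 to 1.06 ± 0.163 (not called without KO1 or with no filter), and the thrombin receptor F2r, from 69.0 ± 14.9 to 29.2 ± 9.26. Reads of Foxl2os and Foxl2 cannot be told apart where they overlap unless strand was used. Mir503, Scarna9, Snord69, Snord19 and Mir7087 were also among the largest falls, but their transcripts are shorter than the fragment length of 200 bp and their values are uncertain.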

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

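The tests of an even rise of all other cell types, of a common fall of the granulosa genes, of a swap of libraries and of the time since hCG were chosen only after the results were seen. Within the WT group 1 of 4 libraries stood far from the other 3 for 6 of 147 measures tested, and chance gives about 1 in 20. Il11 was listed at 0 FPKM in WT2 and lay between 0.513 and 0.575 in the other WT libraries. WT1 stood apart for Gpx3 (89.8 FPKM, others 53.4 to 55.9), Atf3 (20.3, others 9.05 to 9.99), Tspo (7.81, others 9.12 to 9.36) and mt-Rnr2 (161, others 125 to 126). WT4, whose treatment label was that of the KO group, stood apart for Pfkm (6.77, others 8.42 to 8.66).

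Only 1 of the 35 splits of the 7 libraries, the real one, gave as many as 3410 called genes. The highest other gave 2. The same held for the 469 genes changed at least 2-fold, with 1 split and a highest other of 2. These counts set the labelled groups apart, but they cannot exclude chance. With 35 splits the smallest possible permutation p is 0.0286. Each other split also mixes the labels, which widens the spread within its groups and keeps its count low. Chance also cannot be excluded for the number of called lists. There 7 of 35 splits gave at least the real 18, and the highest other gave 19.

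The first pattern is the rise of markers of other cell types in KO-labelled libraries. A lower granulosa share could raise all other types alike, but the lists did not rise by 1 common amount. The median log2 ratio of the macrophage markers, the highest list, rose by 1.78 more (SD 0.629 over 3 libraries) than that of the oocyte markers, the lowest. It rose by 1.42 more (SD 0.305) than that of the stromal markers. The endothelial, smooth muscle, epithelial and erythroid lists lay between, at means of 1.64, 1.41, 1.12 and 1.07. The rule took the highest and the lowest list, and markers also made by granulosa cells would rise less. The gap therefore cannot decide against such a share. These ratios are not on the log2(FPKM + 1) scale used above, on which the gaps are smaller. On that scale the macrophage medians were 2.05, 0.94 and 1.92 in KO1 to KO3. The oocyte medians were 0.22, 0.21 and 0.43, and the stromal medians 0.76, 0.28 and 0.59. A trend with transcript length is argued against, since 98.6% of the raised markers (72 of 73) stayed called and higher after the correction for length. A larger share of particular cells, such as macrophages with C1qa at 15.4 FPKM in KO-labelled libraries, may be behind the pattern, either carried over in preparing the cells or present in the ovary, and these 2 were not tested apart. Of the markers tested, 2 of 19 for macrophages and 2 of 17 for endothelium stood at 5 FPKM or more in WT, and the labels name no sort that would remove such cells.

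The second pattern is the fall of granulosa and FSH-response genes. Dilution by other cells alone would lower all members alike only if those cells expressed none of them. The log2 differences had an SD of 0.464 over 34 genes, above the 0.382 that is 2 times their median standard error. Of the 34 genes 11 were also in another list, and members present in other cells would fall less. The members thus did not fall by 1 common amount, but this cannot decide against dilution. The length trend alone is argued against, though at the edge of the bound set, since exactly 80% of the falls (12 of 15) stayed called after the correction for length and the list median was then -0.49. A later stage after hCG in the KO-labelled mice could give such a fall, and 14 of 42 LH-induced genes were higher, but the median of that list in KO1 (0.16) lay below that in WT4 (0.18), the time to collection is not in the labels and this stays open. An effect of the genotype is also open and was not tested apart from it.

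The third pattern is that Ezh2 was not called lower in KO-labelled libraries. As to a swap of 1 WT and 1 KO library, 0 libraries lay on the other group's side of the first principal component. This argues against a swap only if that component follows the genotype, which was not shown. KO3 stood at 28.6 on it and held the highest Ezh2 value, 26.15 FPKM. Fragments from exons outside the deleted part could keep the whole-gene value up (log2 -0.15), and without values per exon a deletion that leaves the rest of the transcript cannot be told apart from an incomplete one. RNA from cells without Cyp19-Cre activity may add to the whole-gene value and was not tested. The WT group also carried Cre and 1 floxed allele, so by design it could lose Ezh2 from that allele too.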

How the results depend on the processing

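Chosen only after the data were seen were the minimum mean of 5 FPKM, the equal sum of FPKM, quantile normalization, robust empirical Bayes, the fit without short and unannotated genes, the length correction and the permutation of list medians. The count of called genes was 1865 with no filter, where 32922 genes were tested, and the 2-fold count was 780 with a pseudocount of 0.1, which raises the fold of low genes by construction, and 243 with a minimum of 5 FPKM, where fewer genes were tested. Called lists numbered 0 with an estimated correlation (2 at an unadjusted p under 0.05), 0 with the exact permutation of list medians and 13 with fry. Under the other scalings, filters and corrections the 3 counts stayed within 1.5 times. Of the 3410 genes, 2571 were also called with median-of-ratios scaling, 3167 with an equal sum of FPKM and 2247 after the length correction. Il1r2 turned to -0.011 with an equal sum of FPKM, which by construction lowers KO-labelled values against WT (median of all genes from -0.08 to -0.21). The fit without the 20 genes of highest mean holds such a scaling too (median of all genes -0.15). Its shifts therefore cannot be credited to leaving out those genes alone. Ezh2 stayed below 0 and uncalled in every fit run. Il1r2 had no value at a minimum of 5 FPKM.

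With 1 library left out, the called genes ranged from 1293 (without KO1) to 3369 (without WT1), with 2022 without WT2 and 1552 without WT3, and fewer libraries were then compared. The 2-fold genes ranged from 307 (without KO1) to 599 (without KO2), the lists from 15 (without KO2) to 21 (without WT4 and KO3), the Ezh2 difference from -0.30 to -0.04 and that of Il1r2 from -0.032 (without KO1) to 0.23, where KO1 held the highest Il1r2 value of the KO-labelled libraries (2.53 FPKM). No direction of the 141 other named genes turned in any fit. They were named as called genes in these same data, and for each every KO-labelled library lay beyond every WT library. Leaving out a library or changing the pseudocount or filter could therefore not turn a direction. Between 110 of 139 (without KO1) and 139 of 141 (without WT1) stayed called with a library left out, 111 of 141 did with no filter, and under each other setting at most 7 of those tested were lost.

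The numbers of the replicates do not pair the samples by the labels or by the data. Deviations of same-numbered libraries correlated at 0.15, -0.04 and 0.02, and 2 of 6 libraries correlated best with their own number. With the replicate block, which leaves out WT4, 2641 genes were called (2400 shared), 460 of them at least 2-fold, and 20 lists. Steroidogenesis was then not called (adjusted p = 0.0851), the CDK inhibitor, dissociation and histone lists were (0.0396, 0.0282 and 0.0347), and 4 developmental regulators and 5 stromal markers rose and 3 apoptosis genes fell. Of the named genes Tnfrsf10b, Pycard, Irak1, Hist1h1c, mt-Nd4, Sod3 and Mir503 were not called.

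Not run were the planned count tests, the minimum mean count and count-based scaling factors, since the table holds no counts. Counting error was not compared with the spread between libraries, so what depth limits was not tested.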

Other observations

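The tests of X-linked genes after the length correction and of neural regulators, and the choice of the ribosomal protein, small nucleolar RNA, metallothionein and X-linked groups, came only after the results were seen. Antioxidant genes rose in 11 of 25 and fell in 0 (11 and 1 adjusted over the list alone, median 0.33, camera adjusted p = 2.9e-06, and adjusted p = 0.283 with an estimated correlation), among them the plasma glutathione peroxidase Gpx3 at 63.1 ± 17.8 FPKM in WT and 123 ± 6.17 in KO-labelled libraries and the haem oxygenase Hmox1 at 17.0 ± 2.31 and 32.2 ± 7.11. The rises numbered 7 without WT2, 6 without WT3, 4 without KO1, 6 without KO3 and 4 with no filter, and the median was 0.18 with an equal sum of FPKM. In the same libraries macrophage markers rose in 18 of 19, by a median of 1.62. Metallothioneins rose in 3 of 3, with Mt1 at 109 ± 20.8 and 339 ± 135 FPKM. Mitochondrially encoded genes rose in 4 of 15 and fell in 0 (9 and 0 adjusted over the list alone, median 0.43, camera adjusted p = 2.9e-06, and adjusted p = 0.283 with an estimated correlation), and they held 15.4% ± 0.453 of all FPKM in WT and 18.3% ± 0.972 in KO-labelled libraries (two-sided exact permutation p = 0.0286, the smallest possible). Their rises numbered 2 without WT2, 1 without WT3, 2 without KO1, 2 without KO3, 1 with no filter, 2 without the 20 genes of highest mean, 8 with robust empirical Bayes and 10 with a minimum mean of 5 FPKM, and the list was not called with quantile normalization (adjusted p = 0.176), where its median was 0.022, against 0.28 with an equal sum of FPKM. Small nucleolar RNAs fell in 45 of 121 and rose in 0 (median -0.60), values that are uncertain because most of these transcripts are shorter than the fragment length of 200 bp and the libraries were selected for poly(A), while 2 of 81 cytosolic ribosomal proteins rose and 0 fell (median 0.30).

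The remaining lists were not called by camera. CDK inhibitors and p53 targets had 4 higher and 1 lower of 21 (4 and 1 adjusted over the list alone, median 0.12, but from -0.01 with an equal sum of FPKM to 0.22 with median-of-ratios scaling, adjusted p = 0.0531), with the cyclin kinase inhibitor Cdkn1a at 17.9 ± 5.26 and 29.1 ± 3.20 FPKM (limma adjusted p = 0.0431, and 0.0812 to 0.104 without WT3, KO1, KO2 or KO3, and not called with an equal sum of FPKM, no filter, quantile normalization, the length correction or without the 20 genes of highest mean). The higher count was 2, 0, 2, 0, 2 and 0 without WT2, WT3, WT4, KO1, KO2 and KO3, 0 with no filter and 2 with an equal sum of FPKM, where 4 were lower, and the list was called without WT1 (0.0454), WT4 (0.0347), KO1 (0.0414) and KO3 (0.0393), with median-of-ratios scaling (0.0489), after the length correction (0.0392) and without short and unannotated genes (0.0481). Early-response genes of dissociation had 3 higher and 3 lower of 28 (3 and 3 adjusted over the list alone, median 0.16, adjusted p = 0.0556), with the transcription factor Jun at 270.3 ± 37.7 and 161 ± 11.5 FPKM and Atf3 at 12.3 ± 5.33 and 30.8 ± 7.16, and the list was called without WT1 (0.00418, with 9 higher), WT4 (0.0347), KO1 (0.0490, with 1 higher and 1 lower) and KO3 (0.0126, with 1 lower), while 1 was higher without WT3 and the median was 0.10 without WT2. That median was 0.014 with an equal sum of FPKM (3 higher and 5 lower), 0.081 without the 20 genes of highest mean, 0.26 with median-of-ratios scaling (6 higher) and 0.27 after the length correction (5 higher), and with no filter 1 was higher and 1 lower. Sertoli markers had 2 higher and 2 lower of 14 (2 and 2 adjusted over the list alone, median 0.26, adjusted p = 0.0929), with the iron carrier Trf at 24.5 ± 6.22 and 69.1 ± 0.878 FPKM and the ligand Dhh at 16.4 ± 2.49 and 8.20 ± 0.488, and the list was called with no filter on low values (0.0364) and had a median of 0.17 without KO3, 0.16 with an equal sum of FPKM, 0.17 with a minimum mean of 5 FPKM and 0.39 with a pseudocount of 0.1. Its lower count was 1 without each of WT3, KO1 and KO2 and 4 with an equal sum of FPKM, and with no filter 1 was higher and 1 lower. Extracellular matrix genes had 6 higher and 6 lower of 43 (7 and 7 adjusted over the list alone, median -0.00073, mean 0.14, adjusted p = 0.149), and the list was called without WT2 (0.00367, with 11 higher and 3 lower) and after the length correction (0.0392), where its median was 0.29. The lower count was 3 without WT3, 2 without KO1, 2 without KO3, 10 with an equal sum of FPKM, 2 with median-of-ratios scaling and 1 with no filter, and the median was 0.10 with median-of-ratios scaling and -0.10 with an equal sum of FPKM, and lay between -0.057 (without WT1) and 0.17 (without WT2) with a library left out. Histone genes had 1 higher and 0 lower of 13 (0 and 0 adjusted over the list alone, median 0.21, adjusted p = 0.104), and the list was called without WT4 (0.0472) and had a median of 0.12 without KO3, 0.063 with an equal sum of FPKM and -0.044 with no filter, and the higher count was 0 without each of WT3, KO1, KO2 and KO3. Apoptosis genes had 1 higher and 7 lower of 32 (1 and 7 adjusted over the list alone, median -0.05, but from -0.18 with an equal sum of FPKM to 0.03 after the length correction), and glycolysis and hypoxia genes 2 higher and 4 lower of 26 (2 and 4 adjusted over the list alone, median 0.0022, but -0.14 with an equal sum of FPKM, 0.097 with median-of-ratios scaling and -0.11 without KO2), both with adjusted p = 0.803. Without WT2, WT3 or KO1 the lower count of each was 1, and without KO2 it was 4 and 2. With an equal sum of FPKM it was 12 and 9, with no filter 1 and 1, and with median-of-ratios scaling 3 for apoptosis. The lower count was 4 for apoptosis without KO3, where that median was -0.13, and the median was -0.098 without WT4.

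One hypothesis concerned Xist, the RNA that silences an X chromosome, which fell from 47.1 ± 7.29 to 21.7 ± 8.33 FPKM (log2 -1.13, limma adjusted p = 0.0106, and -0.75 with adjusted p = 0.0185 after the length correction of its 17946 bp). If X-linked genes were derepressed they would lie above other genes. Their median over 498 genes was -0.14 against -0.08 in matched autosomal sets, at percentile 0.0400 of 10000 sets, and after the length correction -0.04 against 0.01, at percentile 0.140. Neither value is in line with derepression of X-linked genes.

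Another hypothesis was that developmental regulators are released from PRC2 repression. In the 58 regulators with a mean below 1 FPKM, 43 were higher in KO-labelled libraries, and their median log2 difference of 0.32 lay above all 10000 matched sets (percentile 100, median of the sets -0.03). This is consistent with loss of PRC2 repression, but the median level of these genes was 0.0588 FPKM, below the pseudocount of 0.1 used for them. RNA from other ovarian cells could give the same, and the 15 neural regulators, among them Pax2, which is also known in oviduct epithelium, lay at percentile 98.6 (10 higher, median 0.26 against -0.04). Their median level of 0.0268 FPKM is at the floor, a bound that was added after the percentile was known, so they exclude nothing, and the 2 explanations cannot be told apart here.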
